A study of Homo sapiens with 6 samples.

How the data were processed

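The samples were esophageal tissue from 3 patients with Barrett's esophagus. Each patient gave 1 sample of healthy esophagus and 1 of Barrett's esophagus, a metaplasia in which columnar epithelium replaces the squamous lining. DNA methylation was measured by HELP-tagging. In this assay genomic DNA is cut at CCGG sites in separate reactions with HpaII, which does not cut a methylated site, and with MspI, which cuts whether or not the inner cytosine is methylated. Per the labels' protocols, short tags next to the cut sites were released with EcoP15I, amplified by in vitro transcription and PCR, and sequenced. The same protocol text speaks of DNA from cell lines, while the sample labels name patient tissue. The sample labels were followed.

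The deposited files give 1 score per RefSeq transcript and sample, on a scale from 0 to 100. Genome builds hg18 and hg19 are named in the submitters' processing notes, without saying which step used which. The aligner, the tag filters and the region of a transcript that a score covers are not given in the sources used here. No tag counts or coverage were given for these values, so the depth per sample and per score is unknown, and no counting interval or floor is given.

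The direction of the scale was read from gene classes. Ribosomal protein genes, active in every cell, had a median score of 50.9 or more in each sample and HOX genes 62.4 or more. Germline genes had a median of 27.4 or less and olfactory receptor genes 46.7 or less. A higher score is therefore described as less methylated. This reading rests on these classes and is stated in no label. The germline class holds only 8 genes. The highest olfactory median lay above the median over all genes of any sample, at most 43.7, so that class was not low in every sample. In the 30 distinct autosomal rows that hold a score of 100, 100% of the values in all samples were 0, 50 or 100. Exact values also recurred between genes on different chromosomes, as can happen when a score rests on few sites and few tags, though no table gives their number. A gene with such a value, equal to 6 decimals in a gene of another chromosome, is called a gene with a recurring value. Scores of 0 and of 100 recurred in each sample, so a gene that holds either is included. These were 1137 of the genes (6.08%), among them 214 of the 271 olfactory receptor genes. The tangents of some recurring values double from one value to the next, as in a score made from the arctangent of a ratio. A score point may then stand for different changes in that ratio at low and high scores, so differences at different levels are compared in score points only.

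All 31512 transcripts had a score in each of the 6 samples. RefSeq transcript identifiers were paired with gene symbols of assembly GRCh38.p14, which was used for names, gene types and the choice of autosomes. Of the transcripts, 29981 (95.1%) matched and 1531 did not. Autosomal genes were kept, leaving 28469 transcripts of 18706 genes. A gene's score was the mean over its transcripts. The design, fixed before the data were examined, spoke of CpG sites and promoters. As the files hold neither, transcripts stand for sites and genes for promoters, and gene types stand for genomic contexts.

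Scores as deposited were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend), comparing 3 Barrett's with 3 healthy samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from this test. Single values per sample were compared by two-sided exact permutation tests, which cannot give a p below 0.1 with 3 against 3, or by exact sign-flip tests of the patients' differences, which cannot go below 0.25. The 11 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The estimates ran from 0.0148 in the intestinal list to 0.398 in the HOX list. A call lost in that setting need not mean strongly correlated members. Each list's median difference was also set among 10000 random lists matched on mean score in 20 bins. Figures and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

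The numbers pair the samples, because the labels give each number to 1 patient. In 3 of 3 pairs the deviations from the group means correlated above 0.1. The fit without the patient as a block was the main one and the blocked fit an alternative, both chosen before the data were examined. Other alternatives were leaving out each sample, median centring, quantile normalization, and limma without a trend or with robust settings. Added after seeing the data were a logit transform with an offset of 0.01, a minimum difference of 20, 1 transcript per gene, leaving out genes with a recurring value, and quantile normalization or the estimated correlation combined with the block.

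Genes were named by a fixed rule. AFAP1-AS1 is always named. Up to 12 genes per direction follow, those with the largest mean difference among genes that passed and moved the same way in all 3 patients. Where fewer than 12 passed, the genes with the smallest p, non-overlapping groups and the same sign in all patients fill the places and are named as not passing. Examples come from the list members that passed over their list alone, or the 3 with the smallest p. For transcripts, 5 per direction were taken. The test was checked on simulated data with 18706 genes, of which 200 were changed. It called 6% of the changes of 10 score points, 44% of those of 20, and 78% of those of 30 and of 40, with 8 false calls. The simulated noise was independent between genes and samples, with no library-wide shift and no pairing. The false calls therefore do not measure the error under such effects. The simulated changes were few and went both ways. In the data 5857 genes had an unadjusted limma p under 0.05, 5750 of them higher in Barrett's tissue. The shares called in the simulation therefore do not give the sensitivity of the real comparison.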

Results

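DNA methylation was profiled in healthy and Barrett's esophagus from 3 patients, giving 3 samples per group. Scores of 18706 autosomal genes were compared. A higher score was read as less methylation, from the levels of gene classes. The depth behind the scores is unknown.

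The first comparison asked whether methylation differed over the genome. The mean score over genes was 37.7 ± 0.597 (SD, n = 3) in healthy esophagus and 43.6 ± 1.504 (SD, n = 3) in Barrett's esophagus, a difference of 5.86 ± 0.934 (SE). All 3 patients had the higher mean in the Barrett's sample, by 3.93 to 7.19 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows; paired by patient, exact sign-flip p = 0.25, also the smallest). In score points, the low end of the distribution differed more than the high end. The 10th percentile was 17.8 ± 0.963 (SD, n = 3) in healthy and 26.1 ± 1.65 (SD, n = 3) in Barrett's tissue, while the 90th percentile was 61.1 ± 0.580 and 63.3 ± 2.04. Among 2327 genes with a mean score under 25, the median difference was 7.86, against 0.971 among 3257 genes with a mean score of 55 or more. After each sample was shifted to a common median, the difference in the mean was -0.687. The groups' medians lay 6.54 apart before that shift, and the direction of a gene group with a smaller difference turns with it.

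**Figure D1:**
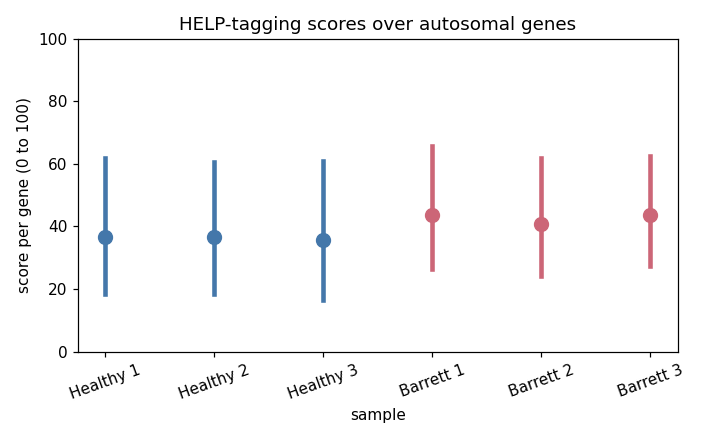
Scores over 18706 autosomal genes (y axis, 0 to 100) in each of the 6 samples (x axis). Points are medians and bars run from the 10th to the 90th percentile. The Barrett's medians lie between 40.9 and 43.7, above the healthy medians of 35.5 to 36.6.

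The study's title names noncoding regions. Introns and intergenic DNA could not be compared, because the values are 1 score per transcript over an unknown region. Gene types were compared in their place, which does not test noncoding regions as such. Long noncoding RNA (lncRNA) genes, 668 in number, scored 40.5 ± 1.03 (SD, n = 3) in healthy and 47.1 ± 1.58 (SD, n = 3) in Barrett's tissue. The 17444 protein-coding genes scored 37.9 ± 0.566 and 43.6 ± 1.51. The difference was 6.55 for lncRNA genes and 5.79 for protein-coding genes. For lncRNA genes it was 0.00719 after median centring and 1.28 after quantile normalization, and for protein-coding genes -0.758 and -0.0738. The excess of lncRNA over protein-coding genes was 0.765 ± 0.284 (SE) larger in Barrett's tissue and was larger in 3 of 3 patients (exact permutation p = 0.1, Benjamini-Hochberg adjusted over 7 comparisons 0.117), and it was 1.35 after quantile normalization. The median difference over genes was 5.08 for lncRNA and 5.00 for protein-coding genes, so the excess was seen in means more than in medians. The 559 transcribed pseudogenes differed by 6.88 and the 35 other RNA genes by 11.4 (exact permutation p = 0.1 for each). After median centring these differences were 0.334 and 4.82, and after quantile normalization 0.813 and 5.21. The test passed for 8.53% of lncRNA genes and for 7.45% of protein-coding genes, a contrast that was not tested.

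AFAP1-AS1, the lncRNA that the title names, is transcribed antisense to AFAP1, an actin filament-associated protein gene. Its score was 19.9 ± 5.09 (SD, n = 3) in healthy and 38.7 ± 8.75 (SD, n = 3) in Barrett's esophagus, a difference of 18.9 ± 5.84 (SE). It was higher in Barrett's tissue in 3 of 3 patients, by 9.55 to 30.1, and the groups did not overlap (exact permutation p = 0.1). The difference was 12.3 after median centring and 11.3 after quantile normalization. Over all genes it did not pass, at an adjusted p of 0.0633 and, with the patient as a block, 0.0849. Among the known lncRNAs it passed adjusted over the list alone, at an adjusted p of 0.0419. In total 768 genes (4.11%) had a larger difference, 55 of them lncRNA genes. AFAP1, chosen after its values were seen, scored 25.5 ± 2.84 and 35.7 ± 4.10, so the difference at AFAP1-AS1 was 8.65 larger than at AFAP1, in the same direction in 3 of 3 patients (exact permutation p = 0.1). Whether both genes share HpaII sites is not known. Leaving out genes with a recurring value gave AFAP1-AS1 an adjusted p of 0.0368, leaving out Barrett's sample 2 gave 0.0339, and its other alternatives ranged from 0.0504 to 0.302.

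The test over genes called 1398 genes, 1388 with a higher score in Barrett's tissue and 10 with a lower score. The largest differences upward were in FGB, the fibrinogen beta chain, KRTAP15-1, a hair keratin-associated protein, and OR1J1, an olfactory receptor, each listed at 0 in all healthy samples and 100 in all Barrett's samples. HBG1, a fetal hemoglobin chain, rose from 15.3 ± 14.6 to 88.2 ± 7.77 (SD, n = 3). GZMA, a protease of cytotoxic lymphocytes, was at 0 in the healthy samples and rose to 58.9 ± 4.57 (SD, n = 3). The rule also took the immune cell genes MS4A2, CD69, GPR171 and IFNA14 and the olfactory receptors OR5M9, OR5D14 and OR52N2. All 12 held a recurring value, that is, a score found exactly in a gene of another chromosome. With the patient as a block, 20 genes passed, all with a higher score, and 18 of them were among the 1398. Of these 20 genes, 15 held a recurring value. After quantile normalization 22 passed, 16 of them with a recurring value, and after median centring 19. The share with such a value was 6.08% over all genes. Leaving out any sample but Barrett's sample 2 left 12 to 52 genes.

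Of the 10 genes with a lower score, SLC7A5, a large neutral amino acid transporter, fell from 64.5 ± 4.04 to 41.1 ± 6.41 (SD, n = 3). SELENOP, a selenium transport protein, fell from 45.8 ± 7.54 to 22.6 ± 6.54. SYT8, a synaptotagmin, fell from 66.5 ± 2.33 to 47.5 ± 2.06, and TP53AIP1, a p53 target in apoptosis, from 57.6 ± 3.57 to 43.3 ± 1.99. The others were GSKIP, which held a recurring value, HOXB1, RPP25L, LRRC55, SSH3 and NOL12, and the adjusted p of the 10 ran from 0.0329 to 0.0493. With the patient as a block none of the 10 passed, at adjusted p from 0.0763 to 0.0862. After quantile normalization SYT8 (limma adjusted p = 0.0458) and GSKIP (limma adjusted p = 0.0305) passed. After median centring SYT8 alone of the 10 passed (limma adjusted p = 0.0317). LY6D, a squamous epithelial surface protein, scored 69.3 ± 5.00 and 44.2 ± 10.9, and SLC25A51P4, a pseudogene, 66.5 ± 1.92 and 52.8 ± 5.15. Neither passed.

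Over single transcripts, 3078 of 28469 passed, 3054 with a higher and 24 with a lower score. With the patient as a block, 23 passed. The 5 named upward were OR1J1, FGB, KRTAP15-1, HBG1 and MS4A2. Downward they were SOX15, a squamous transcription factor gene, at -26.0, LY6D at -25.0, GSKIP, SLC7A5 and SELENOP. LY6D, which has 1 transcript, passed with limma over transcripts (adjusted p = 0.0414) but not over genes (adjusted p = 0.0504).

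Of all genes, 82.6% had a higher score in Barrett's tissue, the share against which counts in a list are read. Genes of intestinal columnar epithelium had higher scores in Barrett's tissue in 46 of 50 members. Adjusted over the list alone 17 passed, all higher, and over all genes 5 passed. OLFM4, an intestinal stem cell marker, rose from 16.3 ± 7.99 to 48.7 ± 6.74 (SD, n = 3), AGR2, a secretory-cell disulfide isomerase, from 23.3 ± 9.65 to 53.9 ± 4.44, and the mucin MUC13 from 19.7 ± 1.29 to 30.8 ± 1.29. The list's median difference was 9.38, above 99.96% of matched random lists (camera adjusted p = 0.0140). The call was lost in camera with an estimated correlation (adjusted p = 0.533). That estimate was 0.0148, near the preset 0.01, so the loss does not show strongly correlated members. In the gastric list 30 of 37 members were higher, and 5 passed adjusted over the list alone and 4 over all genes. TFF2, a mucosal trefoil peptide, rose from 16.6 ± 5.11 to 36.9 ± 3.84, and CLDN18, a gastric tight junction claudin, from 18.3 ± 3.14 to 42.5 ± 8.36. PGC, the pepsinogen C gene, rose from 8.02 ± 2.96 to 29.5 ± 4.14. The gastric list's median difference was 6.52, above 99.4% of matched random lists. The gastric list's camera adjusted p was 0.651, and 0.0180 after quantile normalization. With an estimated correlation, on the scores as deposited, its adjusted p was 0.752. With the patient as a block no member of either list passed over all genes. After median centring the medians were 2.84 for the intestinal and -0.0213 for the gastric list.

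Squamous epithelium genes went both ways, 38 members higher and 20 lower, with an SD of 13.4 over the members' differences. The list's median difference was 2.12 over 58 members, at percentile 0.570 of matched random lists (camera adjusted p = 0.0106, lost with an estimated correlation, adjusted p = 0.533, and after quantile normalization, adjusted p = 0.422). None passed with limma adjusted over the list alone or over all genes, and 12 had an unadjusted p under 0.05. After median centring the list's median was -4.42. The smallest p were those of LY6D, of ESR1, an estrogen receptor, at 28.9 ± 2.18 and 42.5 ± 6.42, and of GJB6, a connexin, at 55.1 ± 2.04 and 64.4 ± 0.942. HOX genes, the developmental patterning genes, had a median difference of -1.46 over 40 members, 24 lower and 16 higher (camera adjusted p = 1.37e-08, lost with an estimated correlation, adjusted p = 0.560, and after quantile normalization, adjusted p = 0.110). The HOX median was -8.00 after median centring. One passed in each direction, by either adjustment. HOXA6 rose from 34.5 ± 3.92 to 51.7 ± 2.52 and HOXB1 fell from 42.8 ± 2.27 to 26.7 ± 2.80. Neither passed over all genes with the patient as a block.

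Markers of other cell types also had higher scores. Of the 35 genes of fibroblasts, muscle and endothelium, 32 were higher, 15 passed adjusted over the list alone and 8 over all genes. The collagen COL3A1 rose from 23.04 ± 2.82 to 47.1 ± 2.97, the matrix proteoglycan DCN from 21.3 ± 5.08 to 46.8 ± 4.08, and the endothelial factor ERG from 27.1 ± 3.19 to 49.0 ± 4.87 (SD, n = 3). The list's median difference was 8.10 (camera adjusted p = 0.0140, lost with an estimated correlation, adjusted p = 0.752). That median lay at percentile 99.56 of matched random lists. It was 1.56 after median centring and 3.00 after quantile normalization, where camera gave an adjusted p of 0.00059. Of 35 leukocyte genes 32 were higher, 5 passed adjusted over the list alone and 3 over all (camera adjusted p = 0.270). The leukocyte median was 7.51, at percentile 95.62 of matched random lists, and 0.967 after median centring. LYN, a kinase of myeloid and B cells, rose from 31.9 ± 1.41 to 42.3 ± 1.52. With the patient as a block no member of these lists passed over all genes.

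**Figure D2:**
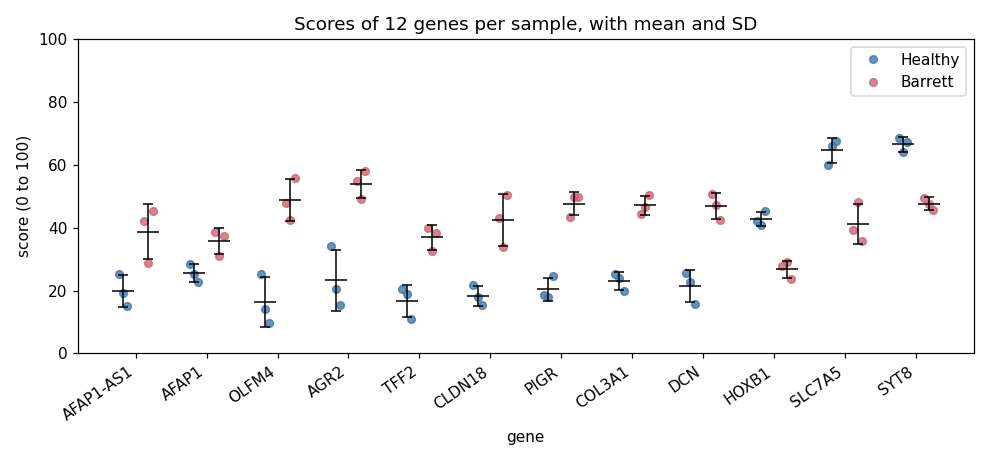
Scores (y axis, 0 to 100) of 12 genes (x axis) in the 3 healthy and 3 Barrett's samples. Dots are samples and black bars the mean and SD per group. AFAP1-AS1 has a mean of 19.9 in healthy and 38.7 in Barrett's tissue, while HOXB1, SLC7A5 and SYT8 are lower in Barrett's tissue.

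Among genes reported as methylated in Barrett's esophagus, 31 of 40 had a higher score, that is, less methylation, and 9 a lower one. For comparison, 82.6% of all genes were higher. The region that a score covers is unknown, so it may not be the region of the earlier reports. The list's median was -2.55 after median centring. Adjusted over the list alone 13 passed, all higher, and 7 over all genes. PIGR, the mucosal immunoglobulin receptor, rose from 20.5 ± 3.65 to 47.6 ± 3.77, WIF1, a Wnt inhibitor, from 25.3 ± 4.39 to 45.3 ± 5.23, and NELL1, a secreted glycoprotein, from 26.3 ± 2.57 to 43.6 ± 3.85. The list's median of 3.99 lay at percentile 52.5 of matched lists (camera adjusted p = 0.950). None passed over all genes with the patient as a block. Of 27 antimicrobial and chemokine genes 20 were higher, and 6 passed adjusted over the list alone and 5 over all. The neutrophil defensins DEFA1 and DEFA3 are near-identical copies with the same scores, 16.1 ± 8.42 and 57.4 ± 4.71. DEFA4 rose from 23.9 ± 4.54 to 61.0 ± 6.68 and TNF, an inflammatory cytokine, from 17.3 ± 4.32 to 37.2 ± 7.68. The antimicrobial list's median was 6.44, and -0.108 after median centring. Its camera adjusted p was 0.950 and after quantile normalization 0.0272, against an adjusted p of 0.979 with an estimated correlation on the scores as deposited. DEFA4 alone passed over all genes with the patient as a block.

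Of 23 known lncRNAs 15 were higher, and 4 passed adjusted over the list alone and 2 over all. These 4 were AFAP1-AS1, CYTOR, CASC2 and MEG3, the maternally expressed imprinted lncRNA, which scored 27.0 ± 1.80 and 39.8 ± 3.89. In the Wnt pathway 38 of 50 genes were higher and none passed adjusted over the list alone with limma (16 at an unadjusted p under 0.05), though WNT2 and TCF7L1 passed over all genes. RNF43, with the third smallest p, did not. Of 33 imprinted genes 25 were higher, none passed adjusted over the list alone with limma (9 at an unadjusted p under 0.05), and MEG3 passed over all genes, ahead of GRB10 and ZIM2. Camera adjusted p were 0.225, 0.579 and 0.270 for these lists, and the blocked fit called none of their members over all genes. In none of these lists was the share of higher members above the 82.6% of all genes. The lists' medians were 2.22, 3.89 and 4.46, and -4.32, -2.65 and -2.08 after median centring.

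**Figure D3:**
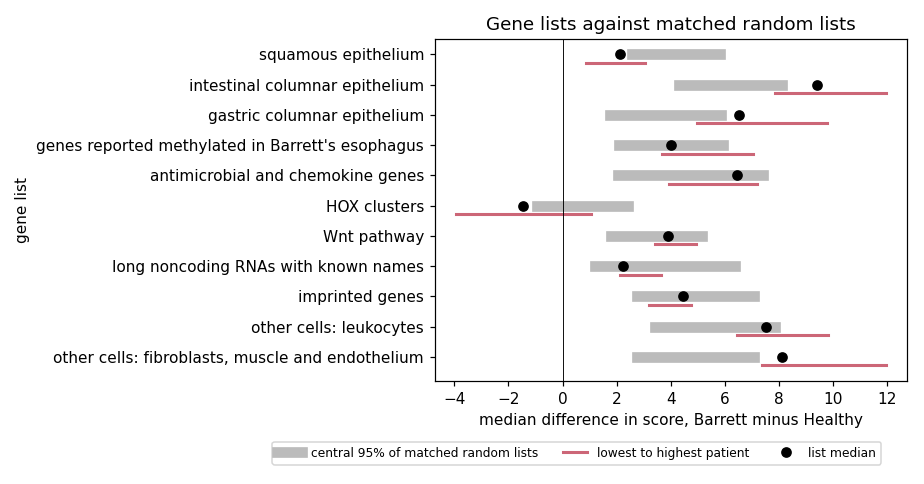
Median difference in score, Barrett minus Healthy (x axis, score points), for the 11 gene lists (y axis). Points are list medians, red bars the lowest to highest patient, and grey bars the central 95% of 10000 matched random lists. The intestinal list lies at 9.38 and the HOX list at -1.46.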

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

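Each test in this part was chosen after the result it measures had been seen.

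The 1531 transcripts without a gene name, which entered no comparison, also had a higher mean score in Barrett's tissue, 40.8 ± 2.04 (SD, n = 3) against 34.0 ± 0.925 in healthy tissue, a difference of 6.77 (exact permutation p = 0.1, the smallest possible).

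Scores were higher in Barrett's tissue over most genes, 82.6% of them (39.4% after median centring, 43.2% after quantile normalization), and in all 3 patients for 51.9%. Groups did not overlap for 6610 genes (35.3%) with the higher score in Barrett's tissue and for 235 (1.26%) with the lower. Chance gives 5% of genes each way if the 6 samples are taken as exchangeable, which leaves out the pairing by patient. All genes come from the same 6 samples, so 1 library-wide difference can move many of them at once. The genes are therefore not independent evidence of a group difference. Without the 1137 genes that held a recurring value the median difference was 4.86, and 3.17 to 5.97 by patient. The higher scores were thus not limited to genes with such a value, which are too few for their removal to bring the median to 1. Other genes may rest on few sites without holding a recurring value, so a part of few-site genes stays open. A library-wide scale or depth stays open too, as no depth is known. After quantile normalization 22 genes passed, but this step removes a technical and a real genome-wide difference alike. Genes at 0 numbered 330 ± 40.3 (SD, n = 3) in healthy and 138 ± 33.5 in Barrett's samples, fewer in all 3 patients. At 0 in all healthy and above 0 in all Barrett's samples were 36 genes, and 0 genes the other way. The SD of scores over genes was 16.9 in healthy and 15.0 in Barrett's samples. The floor and the spread thus also differed between the groups. The tissue difference itself, less methylation in Barrett's esophagus or another mix of cells, cannot be told apart from a library-wide scale or depth.

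Differences of at least 40 score points occurred in 79 genes. Of these, 89.9% held a recurring value, against 6.08% of all genes (exact binomial p = 7.08e-77, with genes taken as independent). Scores on few sites and few tags could give this. Yet any gene with a score of 0 or 100 counts as holding a recurring value, and large differences often begin or end there. The flag and the difference are therefore not independent, and the p does not by itself speak for few sites. Real differences in these genes remain open.

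HOX genes lay below the other genes. High-scoring genes had a small median difference in general, yet the HOX median was at percentile 0.260 of random lists matched on mean score. In 2 of 3 patients it was under percentile 2.5, but in 1 it was at 68.3, and HOX genes are neighbours that move together, so this small difference at high scores cannot be told apart from a change of HOX genes.

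The real grouping called 1398 genes and 3078 transcripts, and the highest other of the 10 splits called 3 and 4. Only 1 split reached each of these counts, the real one. For lists the real grouping called 4 and the highest other 5, and 4 splits had at least as many, the real one included. With 10 splits a share under 0.05 cannot be reached. The 3 other splits that, like the real one, part all 3 patients' pairs called at most 0 genes, 0 transcripts and 4 lists.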

How the results depend on the processing

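The logit transform, the minimum difference of 20, 1 transcript per gene, leaving out genes with a recurring value and the combined settings were chosen after seeing the data. Gene calls (1398) were 19 after median centring, 22 after quantile normalization, 20 with the patient as a block, 18 with both quantile normalization and the block, 2178 without genes that held a recurring value and 257 at a minimum difference of 20. Leaving out 1 sample gave 12 to 1885. The range over transcripts (3078) was 17 to 3779 on leaving out 1 sample, with 27 after median centring, 27 after quantile normalization, 23 with the block, 21 with quantile normalization and the block, and 422 at a minimum difference of 20. The blocked fit has fewer residual degrees of freedom, and centring removes the common shift. List calls (4) were 0 with an estimated correlation, 0 with it and the block, and 2 to 4 on leaving out 1 sample. After quantile normalization 4 lists passed, of which 2 were among the first 4. Under median centring the mean score differed by -0.687 and protein-coding genes by -0.758, and under quantile normalization protein-coding genes by -0.0738. Without these steps the values were 5.86 and 5.79. Pairing by patient cannot change them, since each patient gave 1 sample per group. AFAP1-AS1 differed by 18.9, which pairing cannot change either. It differed by 12.3 after median centring, by 11.3 after quantile normalization and by 15.6 to 23.8 on leaving out 1 sample. After quantile normalization, with and without the block, FABP2 was at -0.250 and CNN1 at -0.0785. On leaving out 1 sample the mean of the genes reported as methylated stood at -1.93 to 0.629 relative to all genes, above 0 without Barrett's sample 3. The cause of these reversals was not tested. Of 96 named genes, 58 passed, 53 of which were lost with the block. Windows of 10 kb, promoter windows, minimum numbers of sites, coverage minimums, count models, sites with values in part of the samples, and the body or upstream region of AFAP1-AS1 were not run, since the files hold 1 score per transcript.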

Other observations

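The gene families in this part were chosen after the data were seen. Cadherins, the cell adhesion genes, had a median difference of 11.5 over 23 members, and 9 passed, all with a higher score in Barrett's tissue. None of the 23 held a recurring value, and the median lay at percentile 99.95 of matched random lists. Potassium channel genes had a median difference of 6.60 over 95 members, 22 of which passed, all higher, at percentile 99.56. UDP-glucuronosyltransferases, which conjugate drugs and bilirubin, had a median of 11.8 over 21 members. Olfactory receptors stood at 14.8 over 271 members, but 214 of them held a recurring value, and the median over the rest was 11.4. Late cornified envelope genes, of the terminally differentiated epidermis, had a median of 21.2 over 15 members.

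Clustered protocadherins, neuronal adhesion genes in tandem arrays, had a median difference of 0.947 over 57 members. None passed with limma, and 1 had an unadjusted p under 0.05. The 492 genes named ZNF had a median of 3.46, at percentile 0 of the matched random lists drawn, and 10 passed, all higher. In the fit with the patient as a block none of the cadherins, potassium channels, UDP-glucuronosyltransferases, late cornified envelope or ZNF genes passed, and 6 olfactory receptors did. Members of a family often lie side by side, which matched random lists do not copy. After median centring the medians were -5.60 for the protocadherins, -3.08 for the ZNF genes, 0.0585 for the potassium channels and 4.98 for the cadherins. The 18 families were not adjusted for their number.

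Among genes without a recurring value, chosen after their values were seen, CFHR4, a complement factor H-related gene, rose from 21.9 ± 2.78 to 66.1 ± 2.18 (SD, n = 3) and passed with the patient as a block (adjusted p = 0.0293). GCSAML rose from 7.22 ± 2.22 to 44.0 ± 5.29 (block adjusted p = 0.0433). TREML5P and LCE2C had larger differences, 48.2 and 45.1, but did not pass with the block (adjusted p = 0.0763 for each).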
